A study of Mus musculus with 5 samples.

How the data were processed

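Gene expression was measured by RNA sequencing in intestinal ILC3 of mice, in single-end reads of 100 bp from cells sorted by subset. The 5 libraries were grouped by their labels into NCR- FM- (2 libraries), NCR- FM+ (2) and NCR+ (1). The labels describe the replicates as biological, 1 to 2 per subset, and p-values measure only the spread between these samples. The deposited count table holds raw read counts per Entrez gene, with replicates kept apart, and these counts were the input of every test. The deposited files per library hold log2 RPKM values made by the authors, which were used only for an alternative fit. Subread, featureCounts and limma are named in the submitters' processing notes together with the builds GRCm38 and mm10, without versions, roles or the strand of counting. Gene coordinates were taken from the RefSeq annotation of GRCm38.

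Each log2 RPKM file was most correlated across genes with the count column of its own library (lowest r 0.855, highest r with another column 0.527, after centring each gene). After gene length was added back, the sorted values of the 5 files nearly coincided (median range 0.0034), so the authors' values carry an adjustment between libraries. These files list 11757 genes. Of 411 X-linked genes above 1 CPM in at least 1 library they list 0, of 167 immunoglobulin genes 0, and of 950 genes with Gm-number or Rik names 4.

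Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr with the subset as group, which left 13775 genes, and libraries were scaled by TMM (factors 0.945 to 1.06). A quasi-likelihood fit with a mean per subset gave 3 comparisons, with 2 residual degrees of freedom, prior degrees of freedom of 2.3 and a common dispersion of 0.152. Calls needed a Benjamini-Hochberg adjusted p under 0.05. In both comparisons with NCR+, the spread came from the NCR- subsets and the lone library was assumed to vary like them. CPM values use TMM-scaled library sizes, mean log2 CPM uses a pseudocount of 0.5, and SE values come from the fitted log2 fold change and its F statistic. Intervals for NCR+ are 95% Clopper-Pearson intervals of the read count in the library total and cover counting error only. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

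The lists, tests, rule for named genes and first set of alternatives were fixed before the data were examined. The 26 lists cover ILC3 regulators, ILC3 cytokines, LTi-like markers, MHC class II, type 1 genes, NK cell receptors, cytotoxic effectors, 2 TGF-β and 2 Notch lists, AhR responsive genes and homing receptors. The others cover ILC2, T cell, B and plasma cell, myeloid, mast cell, epithelial, stromal, erythroid and sex-linked markers, cell cycle, immediate early, interferon and glycolysis genes. Lists with at least 3 tested genes, 25 in all, entered camera with a preset correlation of 0.01, adjusted over the lists of a comparison, and the sex-linked list had too few. Camera compares a list with all other genes, so its direction can differ from the sign of a median. AhR responsive genes did not pass in any comparison, taken in the report's order (adjusted p = 0.961, 0.531 and 0.394), nor did erythroid markers (0.665, 0.199 and 0.235) or glycolysis genes (0.687, 0.242 and 0.171). In the first comparison the AhR test pointed down (median 0.08, mean -0.05). Erythroid markers passed downward in the second without NCR- FM- replicate 2 (0.0332) and in the third without NCR- FM+ replicate 2 (0.0453). Interferon response and immediate early genes did not pass in the first comparison (0.633 and 0.120).

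Genes are named by rule. The 14 fixed genes are Ncr1, Rorc, Tbx21, Eomes, Il22, Il17a, Ifng, Ccr6, Kit, Il7r, Tgfbr1, Tgfbr2, Notch1 and Notch2. Among genes called with values that did not overlap and a mean log2 CPM of at least 2, the 8 with the largest rise and the 8 with the largest fall were to be named. Where fewer than 3 passed in a direction, the 5 with the smallest p were named as not passing, and names starting with Gm and a digit, ending in Rik or made only of an identifier were left out. Up to 4 members with the smallest p were named per list, and any tested member of the TGF-β and Notch lists could be. Genes outside the rule are marked as chosen after their values were seen. Reads of multigene families, such as MHC class II, granzyme, mast cell protease, Klra and Klrb genes, may be assigned to the wrong member.

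Alternatives were DESeq2 size factors in edgeR, scaling by library size only, no filter beyond 1 read, a filter at 5 CPM in at least 1 library, the DESeq2 Wald test and limma-voom. Further ones were a fit of only the subsets compared, glmTreat at a fold of 1.5, leaving out each library in turn, a block for the replicate number, fry, an estimated correlation in camera, and a threshold of 0.1 for overlaps. Robust empirical Bayes, limma-trend on the deposited log2 RPKM values and overlaps of DESeq2 calls were added after the data had been seen. Simulated counts, with each gene drawn on its own, were run through the same code. In these, 200 genes with an average log2 CPM above 2 were changed by 2-, 4- or 8-fold. The edgeR fit recovered 0%, 34.3% and 68.2% of them in the first comparison, 1.49%, 5.97% and 47.0% in the second and 0%, 14.9% and 69.7% in the third. It made 8, 6 and 15 false calls, and DESeq2 made 77, 79 and 70. In 20 simulated draws without change, edgeR called at most 7 genes, and 20 such draws were also run through DESeq2. In 5 draws without change, camera with the preset correlation called at most 2 lists in a comparison. These draws hold no correlation between genes, so they cannot show how many lists camera would call where genes of a list vary together.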

Results

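RNA was sequenced from type 3 innate lymphoid cells (ILC3), lymphocytes of the gut wall that depend on the transcription factor RORγt and make IL-22. Cells were sorted from the intestine of C57BL/6 mice as CD45.2+ cells lacking the T cell marker CD3 and the B cell marker CD19. The 5 libraries fell into 3 subsets. NCR is the natural cytotoxicity receptor NKp46, encoded by Ncr1, and FM, which the labels do not spell out, is read here as a fate map, a lasting mark of cells in which Ncr1 is or once was active. NCR- FM- had 2 libraries, NCR- FM+ had 2, and NCR+ had 1 and thus no replicate. Total counts were 13238711 and 17019769 for NCR- FM- replicates 1 and 2, 12963669 and 11029571 for NCR- FM+ replicates 1 and 2, and 13133025 for NCR+. After the filter on low counts, 13775 genes were tested. Expression is given as CPM, read counts scaled to library size with TMM factors, with the SD between replicates, and differences are log2 fold changes with their SE.

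The series' title names TGF-β and Notch ligands as opposing signals in ILC3 plasticity, so genes of both pathways are reported for every comparison, whatever they showed. In every comparison edgeR called 0 genes at an adjusted p under 0.05, so single genes are described by their values. Lists of genes fixed beforehand were tested with camera, the competitive list test of limma, and are said to rise or fall where they passed it. With a correlation between genes estimated from the data in place of the preset one, camera called 0 of 25 lists in each comparison. That mode of camera also rests on the 2 residual degrees of freedom, so a lost call does not measure correlation alone. In the first comparison the type 1 list had an estimated correlation of -0.049, below the preset 0.01. Its unadjusted camera p still went from 0.000255 to 0.0574. Among the other lists that passed there, the estimate was -0.003 for cell cycle, 0.033 for LTi-like markers and 0.046 for NK cell receptors. It was 0.234 for Notch responsive genes, 0.339 for stromal markers, 0.508 for ILC3 regulators and 0.613 for myeloid markers. B and plasma cell markers had 0.719, epithelial 0.808, mast cell 0.960 and MHC class II 0.983. Where the estimate lies far above the preset, p-values with the preset are likely too small.

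The first comparison, NCR- FM+ against NCR- FM-, asks how NCR- cells with a record of Ncr1 expression differed from NCR- cells without one. Ncr1 (Entrez 17086, GRCm38 chromosome 7, 4337715 to 4345184) measured 0.590 ± 0.499 CPM in NCR- FM- (n = 2) and 5.88 ± 3.29 CPM in NCR- FM+ (n = 2), a log2 fold change of 3.36 ± 0.75, from 13 and 4 reads against 113 and 37. Tbx21 (Entrez 57765, chromosome 11, 97098007 to 97115331), which encodes T-bet, the transcription factor of type 1 lymphocytes, measured 5.09 ± 1.76 CPM against 13.3 ± 0.794, a log2 fold change of 1.38 ± 0.28. Cxcr3 (Entrez 12766, chromosome X, 101731535 to 101734147), a chemokine receptor of type 1 lymphocytes, measured 12.0 ± 1.17 CPM against 41.0 ± 2.30, a log2 fold change of 1.77 ± 0.15. Ccr6 (Entrez 12458, chromosome 17, 8236041 to 8258519), the chemokine receptor that marks LTi-like ILC3, lay the other way, at 253 ± 18.9 CPM against 118 ± 38.0, a log2 fold change of -1.09 ± 0.27. For each of these 4 genes the replicates of the subsets did not overlap.

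Rorc (Entrez 19885, chromosome 3, 94372794 to 94398276), which encodes RORγt, measured 280 ± 36.1 CPM in NCR- FM- and 328 ± 13.3 in NCR- FM+. Kit, the stem cell factor receptor, had a log2 fold change of 0.04 ± 0.20 and Il7r, the IL-7 receptor chain, one of 0.08 ± 0.22. Both turned negative on the deposited log2 RPKM values (-0.094 and -0.011) and without NCR- FM- replicate 1 (-0.030 and -0.074). Il22 (Entrez 50929, chromosome 10, 118204584 to 118210047) varied more between replicates than between subsets, at 1578 and 4928 CPM in NCR- FM- replicates 1 and 2 and 2168 and 6508 CPM in NCR- FM+ replicates 1 and 2. Its log2 fold change of 0.42 ± 0.80 became -0.18 without NCR- FM- replicate 1 and -0.59 without NCR- FM+ replicate 2. Il17a, another ILC3 cytokine, measured 71.4 ± 18.6 CPM against 71.1 ± 43.3, and its log2 fold change of -0.01 ± 0.50 became 0.28 without NCR- FM- replicate 2 and 0.51 without NCR- FM+ replicate 1. Ifng, the type 1 cytokine, had 4 and 2 reads in NCR- FM- and 14 and 9 in NCR- FM+. Eomes, a transcription factor of NK cells, had 6, 7, 6 and 7 reads in these libraries and 9 in NCR+, too few to be tested.

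The 5 genes with the smallest p in each direction did not pass the threshold (edgeR adjusted p from 0.459 to 0.748). On the higher side in NCR- FM+ these were Pcp4, a small calmodulin-binding protein, at 5.54 ± 0.864 CPM against 34.2 ± 5.07 (log2 fold change 2.62 ± 0.21). The others were the smooth muscle genes Acta2 (3.16 ± 0.26) and Myl9 (3.59 ± 0.36), Cxcr3, and Gimap4, a GTPase of lymphocytes (1.40 ± 0.13). On the lower side were Pdcd1, the inhibitory receptor PD-1, at 175 ± 25.7 CPM in NCR- FM- against 69.2 ± 13.0 (-1.34 ± 0.21), and S1pr1, the receptor that guides lymphocytes out of tissue (-0.78 ± 0.15). With them were the G protein regulator Rgs10 (-0.91 ± 0.19), the NAD salvage enzyme Nampt (-0.58 ± 0.12) and the ephrin receptor Epha4 (-1.84 ± 0.40). Across all 13775 genes, edgeR called 0 (smallest adjusted p 0.459), limma-voom called 0 and DESeq2 called 157, 126 higher and 31 lower in NCR- FM+. At an unadjusted p under 0.05 edgeR found 744 genes, 531 higher and 213 lower, where 689 are expected with no difference, and limma-voom found 656. Replicates did not overlap for 2484 genes higher and 2315 genes lower, 34.8% of those tested, against 33.3% by chance. The unadjusted edgeR count was 457 without NCR- FM- replicate 1, 470 without NCR- FM- replicate 2, 1488 without NCR- FM+ replicate 1 and 488 without NCR- FM+ replicate 2, and the adjusted count was 0 in each of these fits. In simulated counts with 200 changed genes, DESeq2 made 77 false calls in this comparison where edgeR made 8.

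By camera, 12 of 25 lists passed, 6 higher and 6 lower in NCR- FM+. The type 1 list rose (adjusted p = 0.00106, and adjusted p = 0.638 with an estimated correlation), with a median log2 fold change of 0.40 over 20 genes. In this list 6 genes were higher and 0 lower at an unadjusted p under 0.05 in edgeR, and 1, Cxcr3, passed adjusted over the list alone, against 0 over all genes. Without NCR- FM- replicate 1, NCR- FM- replicate 2 or NCR- FM+ replicate 1 that count was 2. Ikzf3, the Ikaros-family factor Aiolos, had a log2 fold change of 1.15 ± 0.35. NK cell receptors also rose (adjusted p = 0.00831, and adjusted p = 0.638 with an estimated correlation). Of 27 receptors, 4 passed adjusted over the list alone and 0 over all genes. Among them were the inhibitory receptor Klrc1, at 0.870 and 0.888 CPM in NCR- FM- and 4.07 and 5.28 CPM in NCR- FM+ (log2 fold change 2.40 ± 0.28), the collagen-binding integrin Itga1 (1.95 ± 0.35) and the adhesion receptor Cd226 (0.84 ± 0.16). The NK receptor call was lost without NCR- FM- replicate 2 (adjusted p = 0.156) and without NCR- FM+ replicate 1 (0.490). Its count over the list alone was 0 without either NCR- FM- library, 9 without NCR- FM+ replicate 1 and 2 without NCR- FM+ replicate 2. Cytotoxic effectors did not pass (camera adjusted p = 0.687), with the protease Ctsw at 12.1 and 8.76 CPM against 40.2 and 25.5 and the granule protease Gzmb at 335 and 244 CPM against 159 and 142. In edgeR 0 of 20 passed over the list alone, 3 at an unadjusted p under 0.05, and DESeq2 called 2, while 3 passed over the list alone without NCR- FM+ replicate 1 and 1 without NCR- FM+ replicate 2.

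Genes that respond to Notch signalling rose in NCR- FM+ (camera adjusted p = 0.000136, and adjusted p = 0.638 with an estimated correlation), with a median log2 fold change of 0.38 over 18 genes. The Notch-induced repressors Hey1, at 31.5 and 31.0 CPM against 58.0 and 64.2 (log2 fold change 0.97 ± 0.13), and Heyl (1.29 ± 0.28) passed adjusted over the list alone. So did the Notch regulator Dtx1 (0.91 ± 0.19), the lymphocyte transcription factor Bcl11b (1.25 ± 0.23) and Notch3 (3.32 ± 0.73), 5 of 18 in all against 0 over all genes. That count was 0 without NCR- FM- replicate 1 or NCR- FM- replicate 2 and 3 without NCR- FM+ replicate 1 or NCR- FM+ replicate 2, while the list kept its call in these 4 fits. Hey1, Heyl and Notch3 are also genes of blood vessel cells, and the smooth muscle gene Acta2 measured 1.81 and 2.37 CPM in NCR- FM- and 17.2 and 20.5 CPM in NCR- FM+. The list of Notch receptors, ligands and processing enzymes did not pass (adjusted p = 0.665), with a median of -0.02 where the mean (0.17) and the test pointed up. Notch1 measured 74.9 ± 25.9 CPM against 98.3 ± 28.4 and Notch2 277 ± 13.8 against 257 ± 1.28, and the Notch ligand Jag2 had a log2 fold change of -0.60 ± 0.22.

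Neither TGF-β list passed. TGF-β ligands, receptors and SMADs gave a camera adjusted p of 0.633 and a median log2 fold change of 0.05, with 0 of 20 genes adjusted over the list alone, 1 at an unadjusted p under 0.05 in edgeR and 0 by DESeq2. The receptor chains Tgfbr1 and Tgfbr2 measured 96.4 ± 12.2 and 280 ± 15.0 CPM in NCR- FM- against 87.1 ± 7.50 and 286 ± 16.2 in NCR- FM+. The log2 fold change of Tgfbr2, 0.03 ± 0.15, lay between -0.029 and 0.087 when 1 library was left out. TGF-β responsive genes gave an adjusted p of 0.276, with 0 of 23 genes adjusted over the list alone, 1 at an unadjusted p under 0.05 and 1 by DESeq2. Without NCR- FM+ replicate 1 that count over the list alone was 4. The latent TGF-β binding protein Ltbp4 measured 2.39 and 1.42 CPM against 10.0 and 26.3, and the activin receptor Acvr2a 18.1 and 16.3 CPM against 26.8 and 23.4.

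LTi-like markers fell in NCR- FM+ (camera adjusted p = 0.00420, and adjusted p = 0.638 with an estimated correlation), with a median log2 fold change of -0.29 over 15 genes. In edgeR 0 of these passed adjusted over the list alone or over all genes, 3 were lower at an unadjusted p under 0.05, and DESeq2 called 1. They were Ccr6, Cd4, at 373 and 395 CPM against 158 and 46.4, and the semaphorin receptor Nrp1, at 387 and 419 CPM against 306 and 264. The call was lost without NCR- FM- replicate 2 (adjusted p = 0.156), and 5 genes passed over the list alone without NCR- FM+ replicate 1. MHC class II genes fell as well (adjusted p = 6.70e-06, and adjusted p = 0.660 with an estimated correlation). Their summed expression was 22915 and 8870 CPM in NCR- FM- replicates 1 and 2, 10611 CPM in NCR- FM+ replicate 1 and 505 CPM in NCR- FM+ replicate 2. For 2 of 11 genes the replicates of the subsets did not overlap. Over the list alone 0 of 11 passed in edgeR, with 0 at an unadjusted p under 0.05 and 0 by DESeq2, whereas 11 passed without NCR- FM+ replicate 1.

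Markers of other cell types differed between the same libraries. Myeloid and dendritic cell markers summed to 2581 and 767 CPM in NCR- FM- replicates 1 and 2 and to 1259 and 352 CPM in NCR- FM+ replicates 1 and 2. Without the 3 genes above 10 CPM in NCR+, which made up 321 of the 352 CPM, the sums were 2428 and 657 CPM and 1075 and 30.7 CPM. The whole list fell by camera (adjusted p = 0.00176, and adjusted p = 0.662 with an estimated correlation). Mast cell markers (adjusted p = 8.72e-06, and adjusted p = 0.660 with an estimated correlation) and B and plasma cell markers (adjusted p = 0.00110, and adjusted p = 0.660 with an estimated correlation) fell too. The myeloid and the B and plasma cell calls were lost without NCR- FM- replicate 1 (0.965 and 0.815) and without NCR- FM+ replicate 2 (0.819 and 0.199). The mast cell call was lost without NCR- FM+ replicate 2 (0.113). In each of these 3 lists 0 genes passed over the list alone in edgeR and 0 by DESeq2, with 0, 1 and 1 at an unadjusted p under 0.05. Without NCR- FM+ replicate 1 these counts over the list alone were 13, 13 and 3, and the myeloid count was 1 without NCR- FM- replicate 1. Immunoglobulin genes took 2.31% and 0.108% of counts in NCR- FM- replicates 1 and 2, 0.442% and 0.00568% in NCR- FM+ replicates 1 and 2, and 0.00713% in NCR+.

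Stromal markers rose in NCR- FM+ (camera adjusted p = 7.73e-15, and adjusted p = 0.638 with an estimated correlation), with a median log2 fold change of 2.17 over 17 genes. Besides Acta2, the matrix genes Mgp (log2 fold change 3.24 ± 0.37) and Bgn (3.64 ± 0.49) and the smooth muscle gene Tagln (2.26 ± 0.28) were among 5 that passed over the list alone, against 0 over all genes. That count was 11 without NCR- FM- replicate 1. Epithelial markers rose (adjusted p = 6.87e-12, and adjusted p = 0.647 with an estimated correlation) and summed to 78.1 and 17.6 CPM in NCR- FM- against 318 and 97.4 CPM in NCR- FM+. Of the 23 genes tested, 16 passed the filter on low counts without NCR- FM+ replicate 1, and 16 without NCR+. Part of the rise thus rests on genes that were tested through NCR- FM+ replicate 1 alone. The secretory cell gene Agr2, at 1.81 and 0.355 CPM against 57.4 and 43.1, and the keratin Krt18 were the 2 of 23 that passed over the list alone. This count was 13 without NCR- FM+ replicate 2, 3 without NCR- FM- replicate 1 or NCR- FM+ replicate 1, 1 without NCR- FM- replicate 2 and 4 without NCR+.

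Among the remaining lists of this comparison, ILC3 regulators rose (camera adjusted p = 0.00420, and adjusted p = 0.660 with an estimated correlation), with a median log2 fold change of 0.21 over 19 genes. In edgeR 0 passed over the list alone, 2 at an unadjusted p under 0.05, arginase Arg1 (0.76 ± 0.25) and the transcription factor Zbtb16 (0.62 ± 0.22), and DESeq2 called 0. The call was lost without NCR- FM- replicate 1 (adjusted p = 0.414) and without NCR- FM+ replicate 2 (0.345). Cell cycle genes fell (adjusted p = 0.0453, and adjusted p = 0.638 with an estimated correlation), with a median of -0.26 over 38 genes. In edgeR 0 passed over the list alone and 1 at an unadjusted p under 0.05, the cyclin Ccnb2 (-1.07 ± 0.27), and DESeq2 called 0. That call was lost without NCR- FM- replicate 2 (0.566), without NCR- FM+ replicate 1 (0.881) and with scaling by library size only (0.0661). ILC3 cytokines did not pass (adjusted p = 0.193), but did without NCR- FM- replicate 2 (0.0497) or NCR- FM+ replicate 1 (0.0317). Within that list Csf2, which encodes GM-CSF, measured 9.57 and 10.1 CPM against 25.0 and 32.5 and was the 1 gene of 12 that passed over the list alone, a count of 0 without either NCR- FM- library.

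**Figure D1:**
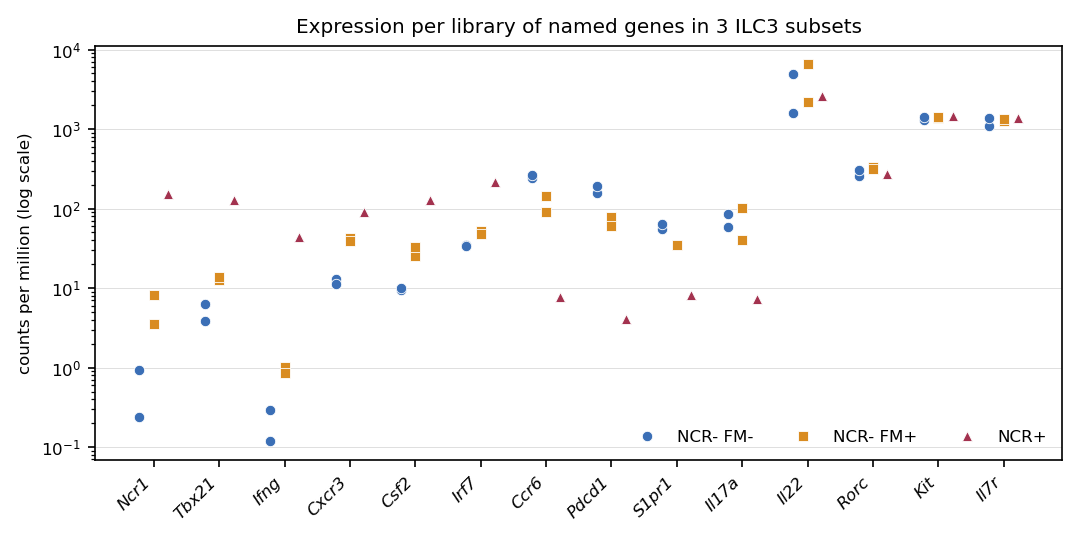
Expression in CPM (log scale) of 14 named genes in each of the 5 libraries, by subset, with 1 point per library. Tbx21 lay at 3.84 and 6.33 CPM in NCR- FM-, 12.7 and 13.8 CPM in NCR- FM+ and 128 CPM in NCR+, and Ccr6 at 240 and 266, 145 and 91.6, and 7.68 CPM.

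The second comparison, NCR+ against NCR- FM-, sets cells that carry NKp46 against NCR- cells without a record of it. Ncr1 measured 150.2 CPM in the single NCR+ library (95% Clopper-Pearson interval of counting error 144 to 157) against 0.590 ± 0.499 in NCR- FM- (n = 2), a log2 fold change of 8.02 ± 0.86. Tbx21 measured 128 CPM (122 to 134) against 5.09 ± 1.76, a log2 fold change of 4.65 ± 0.33. Ifng (Entrez 15978, chromosome 10, 118441046 to 118445894) measured 43.7 CPM (40.1 to 47.5) against 0.204 ± 0.121, and Csf2 (Entrez 12981, chromosome 11, 54247270 to 54249899) 127 CPM (120.4 to 133) against 9.82 ± 0.343. On the other side, Ccr6 measured 7.68 CPM (6.23 to 9.37) against 253 ± 18.9, a log2 fold change of -5.04 ± 0.43. Pdcd1 (Entrez 18566, chromosome 1, 94038305 to 94052553) measured 4.04 CPM (3.01 to 5.31) against 175 ± 25.7, a log2 fold change of -5.44 ± 0.35.

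The cytokines that name ILC3 went different ways. Il17a measured 7.37 CPM in NCR+ against 71.4 ± 18.6 in NCR- FM- (log2 fold change -3.28 ± 0.74), and Il17f 54.4 CPM against 286 and 387 (-2.63 ± 0.41). Il22, at 2638 CPM in NCR+, lay between the 1578 and 4928 CPM of the NCR- FM- replicates, and its log2 fold change of -0.30 ± 0.99 became 0.73 without NCR- FM- replicate 2. The list of ILC3 cytokines did not pass camera (adjusted p = 0.395), while 4 of 12 genes, Csf2, Il17f, Il17a and the lymphotoxin Lta, passed adjusted over the list alone. Without NCR- FM- replicate 2 this count was 1, and it was 6 without either NCR- FM+ library. Rorc, at 271 CPM (262 to 281) against 280 ± 36.1, had a log2 fold change of -0.04 ± 0.21, which became 0.086 without NCR- FM- replicate 2. Kit (0.09 ± 0.24) and Il7r (0.18 ± 0.27) had small positive values that turned negative on the deposited log2 RPKM values (-0.12 and -0.0015).

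None of the 5 genes with the smallest p in each direction passed the threshold (edgeR adjusted p = 0.0733 for each). They included Irf7 (Entrez 54123, chromosome 7, 141263183 to 141266499), the interferon regulatory factor, at 213 CPM in NCR+ against 34.1 ± 0.979 (log2 fold change 2.64 ± 0.15). The others were Pcp4 (4.10 ± 0.24), Csf2 (3.69 ± 0.22), Gimap4 (2.57 ± 0.15) and Cxcr3 (2.90 ± 0.18). On the lower side stood Pdcd1, the integrin adaptor Fermt2 (-3.25 ± 0.23), the Rap GTPase regulator Rap1gap2 (-2.36 ± 0.17), S1pr1 (-2.88 ± 0.21) and the endocytic adaptor Pacsin1 (-6.23 ± 0.46, from 6 reads in NCR+). With edgeR 0 genes were called at an adjusted p under 0.05 (smallest 0.0733) and 129 under 0.1, 76 higher and 53 lower, limma-voom called 0, and DESeq2 called 1199, 547 higher and 652 lower. At an unadjusted p under 0.05 edgeR found 2229 genes, 1162 higher and 1067 lower, where 689 are expected, and limma-voom found 2007. Values did not overlap for 5366 genes higher and 5489 lower in NCR+, 78.8% against 66.7% by chance. The edgeR call count depended on the estimate of spread, being 467 without NCR- FM+ replicate 1, 195 without NCR- FM+ replicate 2 and 357 with only the libraries of these groups in the fit. Without NCR- FM- replicate 1 or NCR- FM- replicate 2 the unadjusted count was 1259 or 1363. In this comparison the lone NCR+ library was assumed to vary like the others.

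By camera, 14 of 25 lists passed, 8 higher and 6 lower in NCR+. The type 1 list rose (adjusted p = 6.19e-11, and adjusted p = 0.218 with an estimated correlation), with a median log2 fold change of 1.35. Of 20 genes 8 passed adjusted over the list alone against 0 over all genes, and 12 without either NCR- FM+ library. Besides Cxcr3, Ifng and Tbx21 these included Xcl1, a chemokine that draws dendritic cells, at 67.0 CPM against 2.18 and 0.888. NK cell receptors rose (adjusted p = 2.02e-10, and adjusted p = 0.218 with an estimated correlation), with a median of 1.39. Of 27 genes 16 passed over the list alone, among them Klrc1 (4.70 ± 0.32), Itga1 (3.88 ± 0.40), Cd226 (1.72 ± 0.18) and the inhibitory receptor Klrg1 (3.07 ± 0.35). Cytotoxic effectors rose (adjusted p = 5.08e-07, and adjusted p = 0.218 with an estimated correlation), with 10 of 20 over the list alone, 6 without NCR- FM- replicate 1 and 5 without NCR- FM- replicate 2. Ctsw measured 388 CPM against 12.1 and 8.76, the death ligand Fasl 18.5 CPM against 0.508 and 0.296, the granzyme inhibitor Serpinb9 3413 CPM against 454 and 557, and perforin, Prf1, 18.4 CPM against 3.63 and 1.83.

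LTi-like markers fell in NCR+ (camera adjusted p = 7.74e-09, and adjusted p = 0.218 with an estimated correlation), with a median log2 fold change of -2.63. Of 15 genes 7 passed over the list alone, 4 without NCR- FM- replicate 2 and 11 without either NCR- FM+ library. Nrp1 measured 52.4 CPM in NCR+ against 387 and 419 (log2 fold change -2.94 ± 0.23), and the follicle-homing receptor Cxcr5 26.5 CPM against 261 and 367 (-3.57 ± 0.36). MHC class II genes fell (adjusted p = 1.37e-06, and adjusted p = 0.571 with an estimated correlation), from sums of 22915 and 8870 CPM to 139 CPM. Of 11 genes 1, H2-Oa, at 2.30 CPM against 103 and 65.8, passed over the list alone, 0 without NCR- FM- replicate 2 and 11 without either NCR- FM+ library. Myeloid markers fell to a sum of 149.5 CPM, of which 135 CPM came from the 3 genes above 10 CPM in NCR+ (adjusted p = 1.30e-05, and adjusted p = 0.616 with an estimated correlation). Mast cell markers fell to 13.9 CPM (adjusted p = 7.74e-09, and adjusted p = 0.571 with an estimated correlation), and B and plasma cell markers to 136 CPM (adjusted p = 0.000252, and adjusted p = 0.626 with an estimated correlation). Their counts over the list alone were 0 of 24, 0 of 13 and 1 of 16 in edgeR, where 2, 9 and 2 passed at an unadjusted p under 0.05 and DESeq2 called 7, 8 and 4. Without NCR- FM+ replicate 1 they were 14, 13 and 3, without NCR- FM+ replicate 2 they were 13, 13 and 3, and the B and plasma cell count was 0 without either NCR- FM- library.

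Notch responsive genes rose in NCR+ (camera adjusted p = 0.00343, and adjusted p = 0.571 with an estimated correlation), with a median log2 fold change of 0.62. Of 18 genes 6 passed over the list alone, against 0 over all genes. Hey1 measured 116 CPM against 31.5 and 31.0 (1.89 ± 0.16), Heyl 13.4 CPM against 1.38 and 1.60, Bcl11b 18.0 CPM against 2.90 and 2.78, and the growth regulator Myc 49.8 CPM against 16.7 and 15.4. Stromal markers moved the same way (adjusted p = 1.44e-10, and adjusted p = 0.363 with an estimated correlation), with 11 of 17 over the list alone and 6 without NCR- FM- replicate 2. In NCR+ Acta2 measured 40.4 CPM, Mgp 10.2, Tagln 43.5 and Bgn 9.11. Epithelial markers did not pass (adjusted p = 0.665), but did without NCR- FM- replicate 1 (0.00155), and their test pointed up where the median and mean were below 0. In edgeR 0 of 23 passed over the list alone, 1, Agr2, at an unadjusted p under 0.05, and DESeq2 called 1, while 1 passed over the list alone without either NCR- FM- library. The list of Notch receptors and ligands did not pass (adjusted p = 0.337). Within it the coactivator Maml3 (-1.77 ± 0.26), the ligands Jag2 (-1.81 ± 0.29) and Dll1 (-2.49 ± 0.50), and Notch3 (3.75 ± 0.80) passed over the list alone. This count of 4 of 24 was 0 without either NCR- FM- library. Notch1 and Notch2 had log2 fold changes of 0.71 ± 0.41 and 0.24 ± 0.17.

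TGF-β ligands, receptors and SMADs did not pass as a list (camera adjusted p = 0.737, median log2 fold change -0.08), and its members went both ways. The ligand Tgfb1 measured 539 CPM in NCR+ against 217 and 231 (1.27 ± 0.27) and Acvr2a 32.9 CPM against 18.1 and 16.3 (0.93 ± 0.21). The accessory receptors Eng, at 36.0 CPM against 87.3 and 117 (-1.51 ± 0.26), and Tgfbr3, at 1.43 CPM against 10.4 and 9.53 (-2.79 ± 0.59), lay lower. These 4 of 20 passed over the list alone, against 0 over all genes, and 0 did without either NCR- FM- library. Tgfbr1 had a log2 fold change of -0.44 ± 0.20 and Tgfbr2 of 0.23 ± 0.18. TGF-β responsive genes gave an adjusted p of 0.737, with a median of -0.16 and a mean of -0.19 where the test pointed up. Of 23 genes 1, the scaffold protein Nedd9 (log2 fold change 1.10 ± 0.16), passed over the list alone. That count was 0 without either NCR- FM- library and 3 without either NCR- FM+ library.

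Interferon response genes rose in NCR+ (camera adjusted p = 0.00122, and adjusted p = 0.376 with an estimated correlation), with 9 of 30 over the list alone, 3 without NCR- FM- replicate 1 and 1 without NCR- FM- replicate 2. Irf7, the GTPase Irgm1 (log2 fold change 1.84 ± 0.21) and Stat1 (0.95 ± 0.14) were higher, and Bst2, which encodes tetherin, lower (-1.81 ± 0.26). Cell cycle genes rose (adjusted p = 0.000198, and adjusted p = 0.218 with an estimated correlation), with a median of 0.62. With edgeR 0 of 38 passed over the list alone, 8 were higher and 1 lower at an unadjusted p under 0.05, and DESeq2 called 2. The proliferation marker Mki67 measured 19.7 CPM against 8.34 and 7.10. Immediate early genes fell (adjusted p = 0.00418, and adjusted p = 0.292 with an estimated correlation), with a median of -0.41. In edgeR 0 of 37 passed over the list alone, 1 was higher and 11 lower at an unadjusted p under 0.05, and DESeq2 called 1 higher and 10 lower. Fos measured 502 CPM against 1441 and 1341, and the signalling regulator Rgs1 1245 CPM against 433 and 449. ILC3 regulators rose (adjusted p = 0.0169, and adjusted p = 0.680 with an estimated correlation), with a median of 0.27. In edgeR 0 of 19 passed over the list alone, 4 were higher and 1 lower at an unadjusted p under 0.05, and DESeq2 called 3 higher. The transcription factor Maf measured 370 CPM against 99.5 and 137, and Zbtb16 104 CPM against 41.3 and 52.3. This call was lost without NCR- FM- replicate 1 (0.196). Of its genes 2 passed over the list alone without NCR- FM+ replicate 1.

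The third comparison, NCR+ against NCR- FM+, sets cells that carry NKp46 against NCR- cells with a record of it. Ncr1 measured 150.2 CPM in NCR+ against 5.88 ± 3.29 in NCR- FM+ (n = 2), a log2 fold change of 4.66 ± 0.73. Tbx21 measured 128 CPM against 13.3 ± 0.794 (3.27 ± 0.32) and Ifng 43.7 CPM against 0.940 ± 0.108 (5.52 ± 0.45). Ccr6 measured 7.68 CPM against 118 ± 38.0 (-3.95 ± 0.41) and Pdcd1 4.04 CPM against 69.2 ± 13.0 (-4.10 ± 0.32). Il17a measured 7.37 CPM against 71.1 ± 43.3 (-3.27 ± 0.74) and Il17f 54.4 CPM against 316 and 480 (-2.87 ± 0.41). Over the list of ILC3 cytokines alone 4 of 12 passed, Csf2, Il17f, Il17a and Lta, and 2 without NCR- FM- replicate 2. The list itself did not pass camera (adjusted p = 0.120), but fell without NCR- FM+ replicate 1 (0.0147). Il22, at 2638 CPM, lay between the replicates of NCR- FM+ at 2168 and 6508, and its log2 fold change of -0.72 ± 1.01 became 0.28 without NCR- FM+ replicate 2. Rorc measured 271 CPM against 328 ± 13.3 (-0.27 ± 0.21) and Il7r had a log2 fold change of 0.10 ± 0.27. ILC3 regulators as a list did not pass camera (adjusted p = 0.316), with a test that pointed down without NCR- FM+ replicate 1 (0.990) and up, past the threshold, without NCR- FM+ replicate 2 (0.0492). Kit had one of 0.05 ± 0.24, which turned to -0.015 with scaling by library size only and -0.028 on the deposited log2 RPKM values.

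Again none of the 5 genes with the smallest p in each direction passed (edgeR adjusted p = 0.215 for each). On the higher side were Irf7 (2.08 ± 0.15), the matrix-associated protein Abi3bp, at 123 CPM against 28.2 ± 4.14 (2.13 ± 0.19), Tbx21, Ctsw (3.56 ± 0.35) and Csf2 (2.14 ± 0.21). On the lower side were Rap1gap2, at 18.9 CPM against 95.5 ± 2.64 (-2.33 ± 0.17), Pdcd1, the sodium channel Scn5a, at 10.8 CPM against 53.7 ± 0.0840 (-2.32 ± 0.19), Fermt2 (-2.72 ± 0.23) and Pacsin1 (-5.19 ± 0.44). With edgeR 0 genes were called (smallest adjusted p 0.215), with limma-voom 0 and with DESeq2 434, 167 higher and 267 lower. At an unadjusted p under 0.05 edgeR found 1348 genes, 597 higher and 751 lower, where 689 are expected, and limma-voom found 1219. Values did not overlap for 4633 genes higher and 4811 lower, 68.6% against 66.7% by chance. The unadjusted count rose without NCR- FM+ replicate 2 and fell without each of the other NCR- libraries.

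By camera, 13 of 25 lists passed, 6 higher and 7 lower in NCR+. NK cell receptors rose (adjusted p = 8.05e-13, and adjusted p = 0.140 with an estimated correlation), with a median log2 fold change of 0.97. Of 27 genes 11 passed over the list alone, against 0 over all genes. Klrg1 measured 35.7 CPM against 5.88 and 4.42, Klrc1 23.1 CPM against 4.07 and 5.28, the receptor Cd244 85.1 CPM against 30.6 and 33.6, and Klri2 79.2 CPM against 17.9 and 17.5. The type 1 list rose (adjusted p = 1.16e-11, and adjusted p = 0.140 with an estimated correlation), with a median of 1.08. Of 20 genes 9 passed over the list alone, among them Stat1, at 222 CPM against 102 and 103, and Xcl1, at 67.0 CPM against 3.49 and 2.11. Cytotoxic effectors rose (adjusted p = 6.53e-11, and adjusted p = 0.140 with an estimated correlation), with a median of 1.65. Of 20 genes 7 passed over the list alone, and 11 without NCR- FM+ replicate 2. Fasl measured 18.5 CPM against 0.290 and 0.288, the granule protein Nkg7 55.4 CPM against 5.16 and 1.63, and Gzmb 413 CPM against 159 and 142.

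Cell cycle genes rose (camera adjusted p = 6.09e-10, and adjusted p = 0.140 with an estimated correlation), with a median log2 fold change of 1.03. Over the list alone edgeR called 0 of 38, 14 were higher at an unadjusted p under 0.05, and DESeq2 called 2. Mki67 measured 19.7 CPM against 6.53 and 5.76, the survivin gene Birc5 6.49 CPM against 1.60 and 1.54, and Ccnb2 10.9 CPM against 3.19 and 3.36. Interferon response genes rose (adjusted p = 5.15e-07, and adjusted p = 0.192 with an estimated correlation), with 3 of 30, Irf7, Stat1 and Irgm1, over the list alone. That count was 8 without NCR- FM+ replicate 2, 2 without NCR- FM- replicate 1 or NCR- FM+ replicate 1, and 1 without NCR- FM- replicate 2. Immediate early genes fell (adjusted p = 2.01e-06, and adjusted p = 0.140 with an estimated correlation), with a median of -0.61. Over the list alone edgeR called 0 of 37, 1 was higher and 13 lower at an unadjusted p under 0.05, and DESeq2 called 9 lower. Fos measured 502 CPM against 1514 and 1169 and Jun 289 CPM against 932 and 717. That list holds genes that respond to cell handling, and sorting times are not given in the sources used here.

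LTi-like markers fell (camera adjusted p = 1.69e-09, and adjusted p = 0.140 with an estimated correlation), with a median log2 fold change of -2.41. Of 15 genes 6 passed over the list alone, and 10 without NCR- FM+ replicate 2. Nrp1 measured 52.4 CPM against 306 and 264 and Cxcr5 26.5 CPM against 246 and 306. MHC class II genes and markers of other cells fell in NCR+ as well. In sums over each list, MHC class II genes measured 139 CPM against 10611 and 505 (adjusted p = 0.000154, and adjusted p = 0.605 with an estimated correlation). Myeloid markers summed to 149.5 CPM against 1259 and 352 (adjusted p = 0.000162, and adjusted p = 0.605 with an estimated correlation). Without the 3 genes above 10 CPM in NCR+ the myeloid sums were 14.2 CPM against 1075 and 30.7. Mast cell markers summed to 13.9 CPM against 546 and 37.3 (adjusted p = 5.57e-07, and adjusted p = 0.605 with an estimated correlation). B and plasma cell markers summed to 136 CPM against 683 and 124 (adjusted p = 0.00349, and adjusted p = 0.605 with an estimated correlation), and NCR- FM+ replicate 2 lay below NCR+. Epithelial markers summed to 42.2 CPM against 318 and 97.4 (adjusted p = 9.30e-06, and adjusted p = 0.605 with an estimated correlation). In these 5 lists 0 genes passed over the list alone in edgeR, 1, 1, 5, 1 and 3 were lower at an unadjusted p under 0.05, and DESeq2 called 2, 1, 7, 0 and 1. Without NCR- FM+ replicate 2 the counts over the list alone were 10, 10, 12, 0 and 2, without NCR- FM+ replicate 1 they were 1, 0, 7, 0 and 0, and the MHC class II count was 1 without NCR- FM- replicate 1. Without NCR- FM+ replicate 1 the B and plasma cell call (0.391) and the myeloid call (0.0929) were lost.

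Stromal markers rose in NCR+ against NCR- FM+ (camera adjusted p = 0.000292, and adjusted p = 0.605 with an estimated correlation), with a median log2 fold change of 1.10. Of 17 genes 2 passed over the list alone. Those were Mgp, at 10.2 CPM against 2.69 and 2.40, and, lower, the pericyte receptor Pdgfrb (-1.13 ± 0.17). The call was lost without NCR- FM+ replicate 1 (0.0727), and the count over the list alone was 0 in each of the 4 fits that left out a library. Notch responsive genes did not pass (adjusted p = 0.250), while 4 of 18, Myc (1.85 ± 0.20), Heyl (1.87 ± 0.31), Hey1 (0.92 ± 0.16) and Bcl11b (1.41 ± 0.26), did over the list alone. That count was 0 without NCR- FM- replicate 2 and 1 without NCR- FM- replicate 1 or NCR- FM+ replicate 1. Notch receptors and ligands gave an adjusted p of 0.394, with a median of 0.24 and a test pointing up where the mean was -0.01. Maml3 (-1.74 ± 0.26) was the 1 of 24 over the list alone, and 0 passed without NCR- FM- replicate 1, NCR- FM- replicate 2 or NCR- FM+ replicate 2. Notch1 (0.32 ± 0.41) and Notch2 (0.35 ± 0.17) did not pass. TGF-β ligands, receptors and SMADs gave an adjusted p of 0.427 and TGF-β responsive genes one of 0.621. Over the list alone edgeR called 0 of 20 and 0 of 23, with 4 and 2 at an unadjusted p under 0.05 and 2 and 1 by DESeq2. For ligands, receptors and SMADs the count was 1 without NCR- FM+ replicate 2. Eng measured 36.0 CPM against 79.1 and 89.5 and Tgfb1 539 CPM against 232 and 335. Tgfbr1 measured 71.0 CPM against 87.1 ± 7.50, Tgfbr2 329 CPM against 286 ± 16.2 and the inhibitory SMAD gene Smad7 64.9 CPM against 103 and 134.

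**Figure D2:**
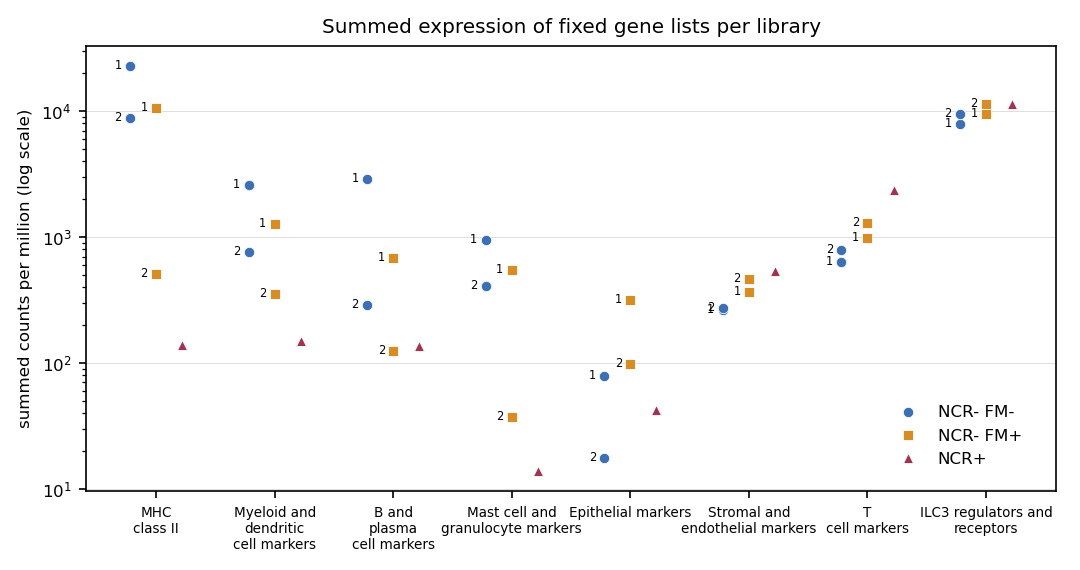
Summed expression in CPM (log scale) of 8 fixed gene lists in each of the 5 libraries, by subset, with 1 point per library and the replicate number beside the points of the NCR- subsets. MHC class II genes summed to 22915 and 8870 CPM in NCR- FM-, 10611 and 505 CPM in NCR- FM+ and 139 CPM in NCR+, while ILC3 regulators and receptors lay between 7890 and 11344 CPM in all 5 libraries.

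Because the 3 comparisons share libraries, overlaps between them lie above chance even where nothing differs. The edgeR calls shared by any pair of comparisons numbered 0, at an adjusted p under 0.05 as under 0.1. At an unadjusted p under 0.05, the first and second comparisons shared 517 genes of the same direction, against 129 in simulated groups without differences that share libraries in the same way (20 draws) and 61.3 if the comparisons were independent. These counts are over all 13775 genes. For the 10136 genes with an edgeR average log2 CPM above 2, the covariance of log2 fold changes was 1.08 against 0.173 in the simulation. Between the first comparison and the third, which share NCR- FM+ with opposite sign, it was 0.330 against -0.179. Among DESeq2 calls, 97 genes were higher and 29 lower in both NCR- FM+ and NCR+ than in NCR- FM-, and 0 went opposite ways. In simulated groups without differences that share libraries in the same way, 7.55 and 4.35 genes on average were shared so, at most 14 and 8 in 20 draws. These draws gave 47.3 and 48.3 DESeq2 calls on average, where the data gave 157 and 1199. Both simulations drew each gene on its own, with no variation shared between genes or by replicate number. They cannot show how much overlap or covariance such shared variation alone would give. Across genes, which are not independent replicates, the correlation of log2 expression was highest between NCR- FM+ replicate 2 and NCR+ (r = 0.974). It was 0.946 between the NCR- FM+ replicates and 0.964 between NCR- FM+ replicate 1 and NCR- FM- replicate 2. NCR- FM+ replicate 1 gave 0.926 with NCR+, and NCR- FM- replicates 1 and 2 gave 0.872 and 0.929. NCR- FM+ replicate 2 and NCR+ also had the lowest MHC class II sums, 505 and 139 CPM.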

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

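The fits with robust empirical Bayes, the fits on the deposited log2 RPKM values, the overlaps of DESeq2 calls and the test of a shared day or batch were chosen after the results had been seen, and the other alternatives were planned.

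The edgeR count of 0 genes in the first comparison, NCR- FM+ against NCR- FM-, stayed at 0 with DESeq2 size factors, library size only, no filter, the stricter filter, limma-voom, only the subsets compared, glmTreat, robust empirical Bayes, the deposited log2 RPKM values and each library left out (0 to 0). The smallest adjusted p over these ran from 0.0791, without NCR- FM+ replicate 1, to 0.793, with limma-voom. DESeq2 called 157 genes, 126 higher and 31 lower. The replicate block, with 1 residual degree of freedom, called 614, 337 higher and 277 lower. All 614 had the same direction without the block, and for 435 the subsets did not overlap. The difference between replicates 1 and 2 was correlated between the NCR- subsets across genes, which are not independent replicates (r = 0.592 over 13775 genes and 0.724 over the 10000 above the minimum mean log2 CPM), and a block takes that shared part out of the spread. The correlation leaves a shared day or batch behind each replicate number open, and the labels do not say what a replicate number shares.

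In the second comparison, NCR+ against NCR- FM-, the count of 0 became 140 without the filter (81 higher, 59 lower), 357 with only the subsets compared (142 and 215), 46 with robust empirical Bayes (26 and 20), 51 on the deposited log2 RPKM values (20 and 31) and 1199 with DESeq2 (547 and 652). Leaving out 1 library gave 0 to 467 genes. A fit without an NCR- FM+ library, or without both, takes the difference between the NCR- FM+ replicates out of the estimate of spread. The cause of the other shifts was not tested. The count stayed at 0 with DESeq2 size factors, library size only, the stricter filter, limma-voom and glmTreat, where the smallest adjusted p ran from 0.0663 to 0.0853. In the third comparison, NCR+ against NCR- FM+, only DESeq2 gave calls (434, 167 higher and 267 lower), and each fit without 1 library gave 0, as did the other alternatives. Overlaps of calls were 0 at both thresholds in edgeR and 126, 35 and 411 among DESeq2 calls.

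Of 25 lists, camera called 12, 14 and 13 in the 3 comparisons, 8 to 12, 14 to 15 and 12 to 15 with each library left out, and 11 in the first with the replicate block or with library size only. With an estimated correlation, a mode that also rests on the 2 residual degrees of freedom, it called 0, 0 and 0. By fry, which asks whether a list moves on balance one way, 1, 1 and 2 lists passed, all higher. Those were the type 1 list in each comparison (fry adjusted p = 0.00605, 0.0130 and 0.00882) and, in the third, cytotoxic effectors (0.0459). Notch responsive genes did not pass by fry (0.423, 0.142 and 0.549). In the first comparison cell cycle genes no longer passed with library size only (adjusted p = 0.0661) or the replicate block (0.149), and the interferon test pointed up with that block (0.719). Homing receptors pointed down by fry in the third (0.782). In each case the cause was not tested.

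For 162 log2 fold changes of named genes, direction and side of the threshold were the same for all 162 with DESeq2 size factors, the stricter filter, limma-voom and glmTreat, and for 161 with library size only. DESeq2 put 119 past the threshold, and of those that the deposited log2 RPKM files list, 132 were the same, 20 passed and 6 turned direction. Past the threshold were also 31 with no filter, 37 with only the subsets compared, 21 with robust empirical Bayes, 40 without NCR- FM+ replicate 1, 32 without NCR- FM+ replicate 2, and 31 of the 48 in the first comparison with the replicate block. Without 1 library 4 (NCR- FM- replicate 1), 3 (NCR- FM- replicate 2), 1 (NCR- FM+ replicate 1) and 3 (NCR- FM+ replicate 2) turned direction. On the deposited log2 RPKM values Kit, Il7r and Tgfbr2 had log2 fold changes of -0.0936, -0.0112 and -0.00888 in the first comparison, Kit and Il7r of -0.122 and -0.00147 in the second, and Kit of -0.0281 in the third, where library size only gave -0.0146. Those RPKM values moved the median of all genes by 0.10 in the second comparison. With each library left out, the first comparison gave log2 fold changes of -0.59 to 1.45 for Il22, -0.82 to 0.51 for Il17a, -0.030 to 0.11 for Kit, -0.074 to 0.25 for Il7r and -0.029 to 0.087 for Tgfbr2. The second gave -0.17 to 0.086 for Rorc and -0.90 to 0.73 for Il22, and the third -1.30 to 0.28 for Il22.

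List tests that turned direction without 1 library had adjusted p values, in the first comparison, of 0.319 to 0.965 (TGF-β ligands, receptors and SMADs), 0.120 to 0.965 (Notch receptors and ligands), 0.354 to 0.778 (T cell), 0.0963 to 0.668 (erythroid), 0.407 to 0.968 (interferon) and 0.411 to 0.965 (glycolysis). In the second it was 0.00155 to 0.702 for epithelial markers, which passed without NCR- FM- replicate 1 and pointed down without NCR- FM- replicate 2 (0.320). In the third they were 0.0492 to 0.990 (ILC3 regulators, past the threshold without NCR- FM+ replicate 2), 0.450 to 0.969 (TGF-β responsive), 0.0849 to 0.990 (both Notch lists) and 0.441 to 0.698 (homing).

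Simulated counts took their library depths and the estimated dispersion of each gene from these data, with each gene drawn on its own. In a single draw per comparison edgeR recovered 34.3%, 5.97% and 14.9% of genes changed by 4-fold in the 3 comparisons. Recovery in the data may be lower. Ncr1 and Ifng, with fold changes of 259 and 210 in the second comparison, were not called. A count of 0 therefore does not show that genes did not differ. Depth was not varied, and its part in this limit was not separated from that of the spread and the number of libraries.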

Other observations

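Every test of an explanation in this part was chosen after the result it examines had been seen.

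Genes of the T cell list went different ways between the subsets. Icos, a costimulatory receptor also carried by innate lymphocytes, measured 321 and 424 CPM in NCR- FM-, 557 and 830 CPM in NCR- FM+ and 1672 CPM in NCR+. The T cell receptor constant genes Trbc1 and Trbc2 measured 91.9 and 221 CPM in NCR+, against 36.1 and 44.5 CPM and 84.8 and 102 CPM in NCR- FM-. Cd3e, which encodes part of the CD3 complex the sort selected against and was chosen here after its values were seen, measured 1.31 and 0.355, 1.09 and 0.0960, and 0.0792 CPM. As a list, T cell markers did not pass camera (adjusted p = 0.687, 0.199 and 0.0997 in the report's order of comparisons), but passed upward in the last without NCR- FM+ replicate 1 (0.0158). The median was -0.27 in the first comparison and -0.19 in the last, where the tests pointed up. Over the list alone 2, 7 and 2 of 18 genes passed. The first of these counts was 0 without NCR- FM- replicate 1, NCR- FM- replicate 2, NCR- FM+ replicate 2 or NCR+, and the middle one was 2 without NCR- FM- replicate 1. The last was 1 without NCR- FM+ replicate 1 or NCR- FM- replicate 1 and 0 without NCR- FM- replicate 2.

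Homing receptors did not pass as a list (camera adjusted p = 0.254, 0.737 and 0.621), and 3, 10 and 6 of 28 genes passed over the list alone. Without NCR- FM+ replicate 1 the first of these counts was 7 and the middle one 16, and without NCR- FM+ replicate 2 the middle one was 16 and the last 12. The first was 1 without NCR- FM- replicate 1, 2 without NCR- FM+ replicate 2 and 0 without NCR- FM- replicate 2, and the last was 4 without NCR- FM- replicate 2. ILC2 markers did not pass either (0.120, 0.310 and 0.615), but fell in the first comparison without NCR- FM+ replicate 1 (0.0242). Over the list alone edgeR called 0, 4 and 3 of 16 genes. In the first comparison 1 was higher and 2 were lower at an unadjusted p under 0.05 and DESeq2 called 0, and in the middle one 4 were higher and 4 lower. The first count was 7 without NCR- FM+ replicate 1, the middle one 9 without either NCR- FM+ library, and the last 7 without NCR- FM+ replicate 2. Hpgds, a prostaglandin synthase of ILC2 and mast cells, measured 7.91 and 8.46 CPM in NCR- FM-, 5.37 and 4.32 CPM in NCR- FM+ and 0.317 CPM in NCR+, while the receptor Klrg1 measured 3.48 and 4.97, 5.88 and 4.42, and 35.7 CPM. The remaining genes of this paragraph were chosen after their values were seen. Cxcr6, a receptor that holds lymphocytes in tissue, measured 482 and 696, 763 and 1275, and 3009 CPM in the same order. The transglutaminase Tgm2 measured 1509 and 1713, 1038 and 1028, and 164 CPM, and the kinase Lck 36.2 and 39.4, 71.9 and 56.9, and 218 CPM. Gapdh, a glycolysis gene, had only 2.54 to 4.13 CPM in the 5 libraries, where the glycolysis gene Pkm had 558 to 842. Whether that low value reflects expression or the assignment of reads was not tested.

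MHC class II genes summed to 22915 and 8870 CPM in NCR- FM- and to 10611 and 505 CPM in NCR- FM+. LTi-like ILC3 express these genes themselves, and so do dendritic cells and macrophages, which the CD3 and CD19 gates of the sort would not remove. Fewer LTi-like cells as the only source ran against the difference between the NCR- FM- replicates, whose median over MHC class II genes, 1.40 on the log2 scale, exceeded that of the highest of Ccr6, Cd4, Nrp1 and Cxcr5 (-0.083) by 1.48. Myeloid cells carried through the sort may account for the pattern in NCR- FM- replicates 1 and 2 and NCR- FM+ replicate 1, where a sum of 21 myeloid genes varied 3.69-fold and the quotient of MHC class II to it 1.43-fold (1.37-fold with all 24 genes, since Lyz1, Xcr1 and Zbtb46, above 10 CPM in NCR+, were left out). For NCR- FM+ replicate 2 the same source stays open, because its quotient was 1.22 times the highest of these without the 3 genes and 0.124 times with them. The quotient does not single out myeloid cells, because markers of other cells ranked the NCR- libraries in the same order. Mast cell markers summed to 950 and 410 CPM in NCR- FM- replicates 1 and 2 and 546 and 37.3 CPM in NCR- FM+. B and plasma cell markers summed to 2892, 287, 683 and 124 CPM in the same libraries. Cd74 measured 8157, 3013, 3862 and 208 CPM and the macrophage gene Lyz2 650, 76.0, 267 and 6.34 CPM in the 4 NCR- libraries, and a difference in MHC class II of the ILC3 themselves stays open.

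Il22 was lower in the replicate 1 libraries of both NCR- subsets, by log2 differences of -1.64 and -1.59. Dilution of ILC3 RNA by other cells would lower ILC3 regulators as much, but the lowest of that list differed by -0.68 and -0.75 and the median by -0.26 and -0.28, so that Il22 lay below the lowest gene in both subsets, by -0.836 in the subset with the smaller gap. What the libraries of 1 replicate number shared is not given in the sources used here, and with 2 libraries per subset no biological explanation was tested.

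Epithelial genes were higher in NCR- FM+, with values above both NCR- FM- libraries in both replicates for 12 of 23 genes, and Epcam, at 28.1 and 4.91 CPM in NCR- FM- against 24.0 and 8.16, was not among them. Epithelial cells or their RNA carried through the sort, of which a CD45.2 gate would remove intact cells, and an epithelial program of the NCR- FM+ cells cannot be told apart, because that count restates the pattern and either would give it. The spread between the NCR- FM+ replicates leaves both open as well, with a median log2 difference of 2.14 over the list, where 20 of 23 genes were at least 2-fold apart, and of 0.49 over 7 genes of gland cells, chosen after their values were seen, where 6 were under 2-fold apart. Only 16 of the 23 list genes passed the filter on low counts without NCR- FM+ replicate 1. The rest were tested through their counts in that library, so the filter itself favours a higher replicate 1 in this list. Of these 7 the mucin Muc6 measured 3.55 and 0.769 CPM in NCR- FM-, 749 and 535 CPM in NCR- FM+ and 158 CPM in NCR+, the trefoil peptide Tff2 24.2 and 1.89, 1469 and 858, and 311 CPM, and the pepsinogen Pgc, the 1 further apart, 0.653 and 0, 51.6 and 10.2, and 40.6 CPM. Cftr, Aqp5, A4gnt and Spdef measured 0 to 0.118 CPM in NCR- FM-, 5.47 to 14.9 CPM in NCR- FM+ and 0.554 to 4.44 CPM in NCR+.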
